A study of Mus musculus with 6 samples.

How the data were processed

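RNA from the vastus lateralis muscle, a part of the quadriceps, of 6 mice was measured on Illumina mouse bead arrays, with 1 array per sample. Per the labels' protocols, RNA was extracted with a fibrous tissue kit, treated with DNase I, checked on a Bioanalyser, and turned into biotinylated cRNA with the Ambion MessageAmp kit. The labels place 3 samples (Sample906, Sample872 and Sample923) in the wild type group and 3 samples (Sample873, Sample874 and Sample871) in the FRG1 transgenic group, and give all of them as C57Bl/6J females aged 4 weeks. The sample numbers are not shared between the groups, so no pairing was fitted. The labels number the samples but do not describe how the animals were bred or in what order they were handled, so the p-values measure only the spread between these samples.

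The authors deposited 2 tables. The first holds, per the file headers, a signal intensity and a detection p-value for each of 46632 probes on each array, with no normalization, and all of the signal intensities are above 0. The second holds the authors' processed intensity for the same probes. Per the submitters' processing notes the lumi package was used, and its version and settings are not given in the sources used here. Set against the signal intensities, the processed values of each array kept the rank order of the probes, between 33.7% and 33.9% of them lay below 0, and the column medians lay between 5.07 and 5.15. These are the marks of a linear scale after background subtraction and scaling to a shared distribution, and what the authors subtracted stays unknown. The processed table was used as an alternative only.

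The signal intensities were corrected for background and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with the negative control distribution inferred from the detection p-values and an offset of 16, and were taken to log2. A probe was retained when its detection p was under 0.05 on at least 3 of the 6 arrays, which left 19563 probes. Each retained probe was fitted with lmFit and eBayes of limma, with the group as the only term, and two-sided p-values were adjusted by the Benjamini-Hochberg method over the retained probes, with a threshold of 0.05. A positive log2 fold change means a higher value in transgenic muscle. Fold changes of dim probes are understated by the offset. The number of arrays limits the precision of every value.

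Probes were named from the platform's annotation, and symbols were updated through their Entrez gene to the RefSeq table of assembly GRCm38.p6, in which 29921 probes were matched. Of all probes, 29976 had 1 gene symbol, 10 had several and 16646 had none there. No probe with several symbols was given a name. Of the retained probes, 14808 had 1 symbol and stood for 10287 genes, and the probe with the highest mean over the 6 arrays represented a gene. Among genes past the threshold with several retained probes, 551 in number, 129 had a retained probe of the opposite sign and 12 had one that itself passed the threshold. The labels and the tables of array values name no genome build, so no coordinates are printed, and the RefSeq table served only for names, for which genes share a chromosome and for gene span.

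Where a probe was above background on none of the 3 arrays of a group, its fold is given as a bound. The mean of the brighter group was set against the mean, over the arrays of the dim group, of the higher of 2 values, the lowest signal of a detected probe and the probe's own value. No fold is given where both groups were below background.

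The genes named were chosen by a rule fixed before the data were examined. It takes Frg1, the 12 largest positive and the 12 largest negative log2 fold changes among genes past the threshold whose groups did not overlap (clone and prediction names left out), up to 4 members with the smallest p of each gene list, and Rbfox1, Eid3, Capn3, Tnnt3, Kmt5b and Xist. Members beyond these, and genes named in the closing section, were chosen after their values were seen. Also fixed beforehand were 32 gene lists of muscle, metabolism, stroma, cell type, stress, handling and RNA genes, and 31 of them had at least 5 measured genes. They were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. A list's counts are given over all retained probes and adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction without setting them against other genes, were alternatives.

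The fit was tested on simulated data with the means and spreads of the 19563 retained probes and changes added to 100 probes at each of 2 sizes. It recovered 61% of the probes changed by 1 log2 unit and 18% of those changed by 0.6, with 3 calls among unchanged probes, and made 0 calls when nothing was changed. When 1 list was raised, that list and 1 other were called. The simulated probes were drawn independently, and far fewer were changed than the 2702 that passed in the real data. The recovered shares are therefore not the power of the real fit. The list check holds no correlation between genes, so it cannot vouch for the preset correlation.

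Other background corrections, normalizations, detection filters, variance models, array weights, averaging of a gene's probes, the authors' processed values and leaving out each sample were tried as alternatives. A slide block was planned, but the tables name no slides, and it was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.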

Results

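Expression was measured in vastus lateralis muscle of 3 wild type mice and 3 mice that overexpress FRG1 (FSHD region gene 1, named for its position near the repeat array linked to facioscapulohumeral muscular dystrophy). All were females aged 4 weeks. The comparison asks which transcripts differ in muscle when FRG1 is in excess. The summed signal of an array lay between 10537335 (wild type Sample923) and 13062182 (transgenic Sample873) intensity units. Between 17957 probes (wild type Sample923) and 20000 probes (transgenic Sample873) were detected above background. Across retained probes, Pearson correlations of log2 values were 0.990 to 0.993 between transgenic samples, 0.982 to 0.991 between wild type samples, and 0.966 to 0.980 between groups. The first principal component held 56.9% of the variance and separated the groups. The second held 19.2% and set wild type Sample923, with a score of 27.8, apart from wild type Sample906 at -21.2 and wild type Sample872 at -14.9.

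**Figure D1:**
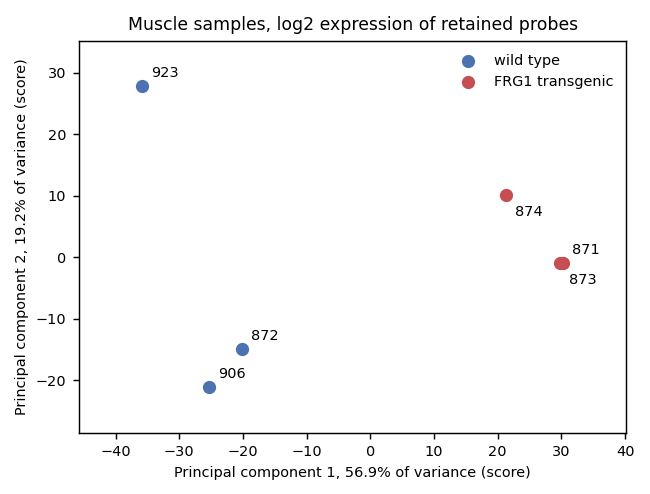
Scores of the 6 samples on the first and second principal components of log2 expression over retained probes, with points labelled by the number in the sample name and coloured by group. The groups part along the first component (56.9% of the variance), and wild type Sample923 lies apart from the other wild type samples along the second (19.2%).

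The array carried 1 Frg1 probe (ILMN_1240867), and it was detected above background on 0 of the 6 arrays, with a lowest detection p of 0.122. Its raw signal was 40.9 ± 4.84 intensity units in wild type muscle and 42.3 ± 3.29 in transgenic muscle (SD, n = 3 each). The labels do not say whether the transgene is of mouse or human sequence. The probe did not detect the mouse's own transcript in wild type muscle either, so it checks neither the transgene nor the labels, and no fold is given. Of the probes for Y-linked genes, those of Eif2s3y and Kdm5d were detected on 0 of the 6 arrays, whereas 1 of the 3 Uty probes was detected on all 6. Xist, the transcript of the inactive X chromosome in females, was detected on all 6 arrays by 1 of its 2 probes. The log2 fold change of that probe, 0.40 ± 0.40 (SE), did not pass the threshold in limma (adjusted p = 0.557).

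The transcripts that rose most in transgenic muscle included developmental isoforms of the contractile apparatus. Myh8, the perinatal myosin heavy chain (ILMN_1223735), rose 18.5-fold, from a log2 value of 7.12 ± 0.12 in wild type to 11.33 ± 0.08 in transgenic muscle (SD, n = 3 each; limma adjusted p = 2.34e-07). Myl4, a myosin light chain of embryonic muscle and the atrium, rose 7.78-fold (log2 fold change 2.96 ± 0.16, SE; adjusted p = 8.19e-06). Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 7.43-fold, and its 3 wild type values were the most scattered of these genes (9.82 ± 0.95 against 12.71 ± 0.19; limma adjusted p = 0.00102, SD with n = 3 each). Eda2r, a receptor for ectodysplasin A2, rose 6.76-fold, and Lgals3, the lectin galectin-3, rose 6.02-fold. Rrad, a small GTPase that restrains voltage-gated calcium channels, rose 6.48-fold, and it was above background on 2 of the 3 wild type arrays. Cpne2 rose 8.12-fold, Vash2 7.47-fold, Zfp365 6.24-fold and Kcne1l 5.96-fold. For Zfp365 1 of its 2 retained probes passed, and its log2 fold change of 2.64 was 1.52 with its probes averaged. Clca4a and Catsper4, the latter a subunit of the sperm calcium channel, were above background on none of the wild type arrays and were at least 6.83-fold and at least 6.34-fold higher. Adjusted p-values of these 12 genes lay at or below 0.00102.

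Decreases were smaller. Chac1, an enzyme that degrades glutathione, fell most, with a value 6.01-fold higher in wild type muscle (log2 10.58 ± 0.66 in wild type and 7.99 ± 0.60 in transgenic muscle, SD, n = 3 each; limma adjusted p = 0.00123). Gpcpd1, a glycerophosphocholine phosphodiesterase, was 3.70-fold higher in wild type and fell on 4 of its 4 retained probes. Ppp1r1a, an inhibitor of protein phosphatase 1, fell with a wild type value 3.18-fold higher. The homeobox gene Barx2 was 3.11-fold (above background on 2 of the 3 transgenic arrays) and Ddah1, which degrades methylated arginines, 3.03-fold higher in wild type. Ache, the acetylcholinesterase of the neuromuscular junction, was 2.72-fold higher in wild type, and Myl3, the light chain of slow and ventricular myosin, 2.65-fold higher. Capn3, the muscle calpain mutated in a limb-girdle dystrophy, was 2.54-fold higher in wild type, and 1 of its 2 retained probes passed. Magix and Dnaja2, a co-chaperone, were 2.49-fold and 2.47-fold higher in wild type. Pnck and Fgfbp1 were above background on none of the transgenic arrays and were at least 2.36-fold and at least 2.24-fold higher in wild type.

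**Figure D2:**
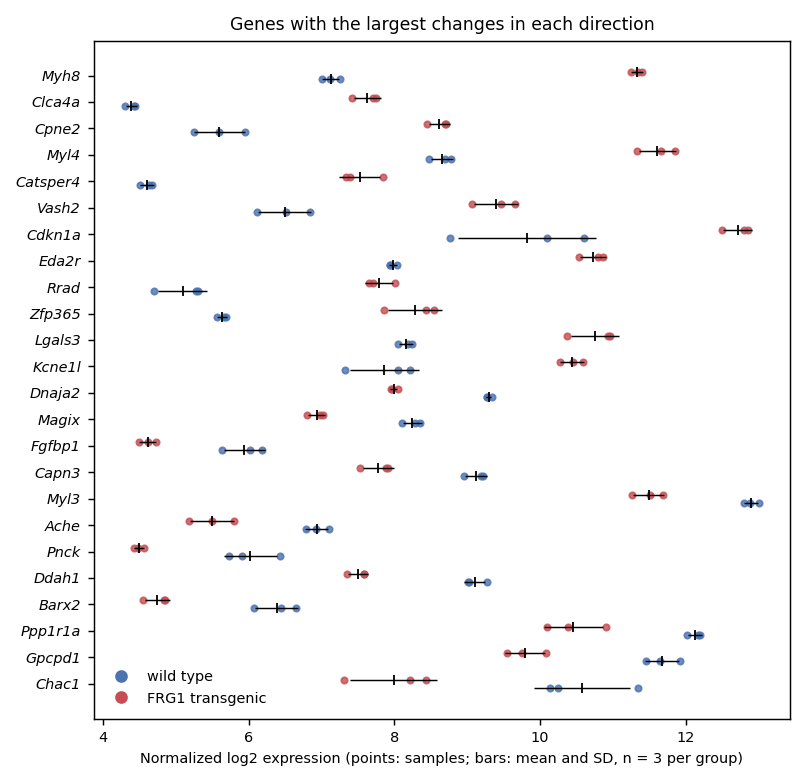
Normalized log2 expression (horizontal axis) of the 12 genes with the largest increase and the 12 with the largest decrease, with 1 point per sample and bars for the mean and SD of each group (n = 3). The 3 transgenic values lie on 1 side of the 3 wild type values in each gene, from Myh8 (log2 fold change 4.21) at the top to Chac1 (-2.59) at the bottom.

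In all, 2702 of the 19563 retained probes passed the threshold in limma, 1389 higher and 1313 lower in transgenic muscle (51.4% higher). Changes of at least 2-fold were more often increases, with 366 probes higher and 106 lower. At the gene level 1519 of 10287 genes passed, 775 higher and 744 lower. The groups did not overlap in 3770 genes (36.6%), against 10% by chance for 3 against 3. With median scaling in place of quantile normalization, which shifted the median log2 fold change of all probes by 0.13, the split was 1923 higher and 507 lower (79.1% higher). With 1 sample left out, 1161 probes passed without transgenic Sample873, 1181 without transgenic Sample871, 1774 without transgenic Sample874, 1860 without wild type Sample906, 2152 without wild type Sample872 and 2660 without wild type Sample923.

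In the lists of developing and of denervated muscle most measured genes were higher. The regeneration and embryonic muscle list had a median log2 fold change of 0.75, or 0.71 with the member below background in wild type at its bound. Without transgenic Sample871 the median was 0.48. Of its 13 measured genes, 8 were higher and 1 was lower (9 higher and 1 lower when adjusted over the list alone). Besides Myh8 and Myl4 these were led by Chrng, the fetal subunit of the acetylcholine receptor (2.54 ± 0.21, SE, above background on 1 of the 3 wild type arrays, so that its size is uncertain), and Ncam1, a neural cell adhesion molecule (1.59 ± 0.14), of which 1 of 4 retained probes passed and which lost its call when probes were averaged. The camera adjusted p was 1.09e-07, and adjusted p = 0.25 with an estimated correlation. The denervation response list had 9 of 11 measured genes higher and 0 lower (10 higher when adjusted over the list alone), with a median of 1.18. It shares Chrng, Ncam1 and the myogenic factor Myog with the list before. Mustn1 rose by 1.26 ± 0.13 on the log2 scale, and Ankrd1, a stretch-responsive muscle protein, by 1.21 ± 0.14. Its camera adjusted p was 1.64e-09, and adjusted p = 0.25 with an estimated correlation.

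Genes of slow fibres moved in both directions. Of 12 measured slow fibre genes 5 were higher and 1 was lower (6 and 2 when adjusted over the list alone), with a median of 0.37. Tnnt1, slow troponin T, rose by 1.37 ± 0.17 and Csrp3, a Z-disc protein, by 1.40 ± 0.20, while Myl3 changed by -1.40 ± 0.14 (SE, log2). The camera adjusted p of 0.0335 became adjusted p = 0.547 with an estimated correlation, and the call was also lost with cyclic loess or median scaling and without wild type Sample872, wild type Sample923 or transgenic Sample871. Of 13 fast fibre genes 0 were higher and 3 lower (3 also when adjusted over the list alone), among them the alpha-actinin Actn3 (-0.79 ± 0.12) and Myh4, the type IIB myosin heavy chain (-0.45 ± 0.13, a call lost under 7 of 16 alternatives). Their median was -0.02 and the list did not pass (camera adjusted p = 0.267), though it passed downward with median scaling (adjusted p = 0.0102) and with fry (adjusted p = 0.0441). Tnnt3, fast troponin T, had a log2 fold change of 0.01 ± 0.12 (adjusted p = 0.983).

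Markers of other cell types moved in different directions. Of 14 measured macrophage markers 12 were higher and 0 lower (13 higher when adjusted over the list alone), with a median of 0.66. They included Lgals3, the protease Ctss (1.03 ± 0.14), lysozyme Lyz2 (1.06 ± 0.15) and the Fc receptor chain Fcer1g (0.85 ± 0.13). The camera adjusted p was 5.86e-10, and adjusted p = 0.25 with an estimated correlation. Endothelial markers had 0 of 15 higher and 3 lower (5 lower when adjusted over the list alone), with Cldn5, a tight junction protein, at -0.76 ± 0.18 and the coreceptor Eng at -0.57 ± 0.14, calls lost under 6 of 16 alternatives for each. Smooth muscle and pericyte markers had 0 of 12 higher and 4 lower (7 lower when adjusted over the list alone), with the channel subunit Abcc9 at -0.92 ± 0.14 and the kinase Mylk at -0.78 ± 0.13. Tendon and junction markers had 0 of 9 higher and 6 lower (6 also when adjusted over the list alone), with tenomodulin Tnmd at -0.89 ± 0.13 and keratocan Kera at -1.09 ± 0.23 (lost under 4 of 16 alternatives). These 3 lists had medians of -0.40, -0.37 and -0.62 and camera adjusted p-values of 0.00218, 0.00300 and 0.00218, and each had adjusted p = 0.25 with an estimated correlation.

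The interferon, p53 target, heat shock and immediate early lists also passed at the preset correlation. Of 17 interferon response and antigen presentation genes 4 were higher and 0 lower (4 higher when adjusted over the list alone). All 4 act in antigen presentation by MHC class II: H2-Aa (1.54 ± 0.13), H2-Ab1 (1.57 ± 0.20), H2-Eb1 (1.53 ± 0.16) and the invariant chain Cd74 (1.54 ± 0.18). The list median was 0.07, the camera adjusted p of 0.0264 became adjusted p = 0.25 with an estimated correlation, and the call was lost without wild type Sample906 or wild type Sample923. Of 9 p53 target genes 3 were higher (6 when adjusted over the list alone), namely Cdkn1a, Phlda3 (1.21 ± 0.13) and the p53 ligase Mdm2 (0.86 ± 0.12, or 0.52 with its probes averaged), with a median of 0.35 that was 0.15 with no detection filter. The camera adjusted p was 0.00218, and adjusted p = 0.25 with an estimated correlation. Of 8 heat shock genes 3 were higher (4 when adjusted over the list alone), the small heat shock proteins Hspb1 (1.09 ± 0.14), Hspb8 (0.90 ± 0.13) and Cryab (0.47 ± 0.13, a call lost under 8 of 16 alternatives), with a median of 0.32 that was 0.12 with no detection filter. The camera adjusted p of 0.0131 became adjusted p = 0.418 with an estimated correlation, and the call was lost with median scaling. Of 11 immediate early genes 2 were higher (4 when adjusted over the list alone), Fos (1.09 ± 0.20) and Atf3 (1.53 ± 0.29, above background on 2 of 3 wild type arrays), both calls lost with no detection filter, with a median of 0.41 that was then 0.20, a camera adjusted p of 0.00681, and adjusted p = 0.25 with an estimated correlation.

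**Figure D3:**
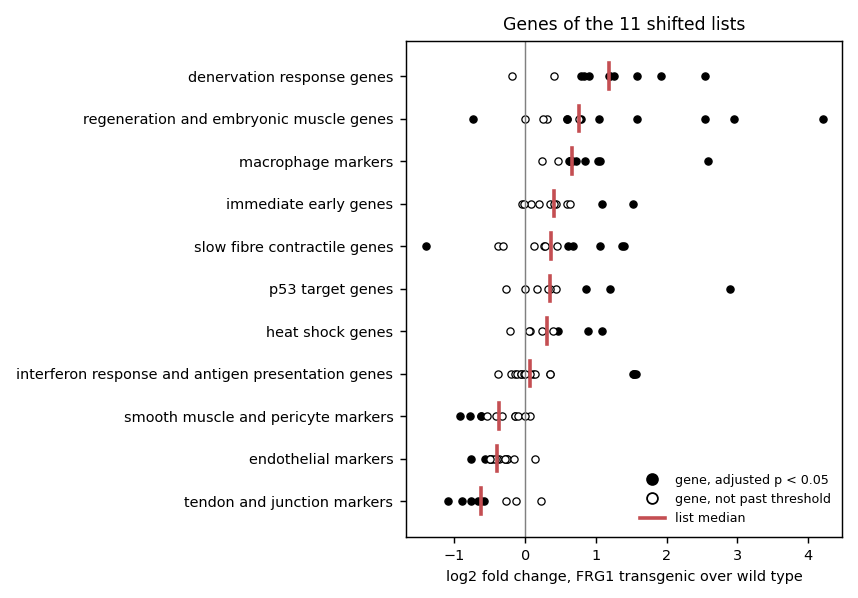
Log2 fold change (transgenic over wild type, horizontal axis) of each measured gene in the 11 lists that passed camera at the preset correlation. Filled points passed the limma threshold, open points did not, and the vertical bars are list medians, from 1.18 for the denervation response list to -0.62 for the tendon and junction list.

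Of the 31 lists tested, 11 passed at the preset correlation, 8 upward and 3 downward. With an estimated correlation camera called 0 lists, although 6 had an unadjusted p under 0.05, and fry called 14. The estimated correlations of the p53 (-0.093) and interferon (-0.021) lists lay below the preset 0.01. Their unadjusted camera p still rose, from 0.000388 to 0.0210 and from 0.00852 to 0.0472. A higher correlation between genes thus cannot account for the loss of these calls. Another division of the same 6 samples, which mixed the genotypes, gave 12 lists at the preset correlation.

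The other 20 lists tested did not pass camera. In 3 of them the signs differed between measures: the atrophy and autophagy list had a median of 0.01 and a downward test, the sarcolemma list a median of -0.06 and an upward test, and the splicing regulators a median of -0.15 and a mean of 0.03. Among muscle and metabolic lists, 4 of 15 atrophy and autophagy genes passed (2 higher, the metallothioneins Mt1 at 1.07 ± 0.14 and Mt2 at 1.21 ± 0.19, and 2 lower; camera adjusted p = 0.928). Of 18 sarcolemma and dystrophy genes 3 were higher and 3 lower (adjusted p = 0.988), with caveolin Cav3 at 0.85 ± 0.12, sarcoglycan Sgca at -0.79 ± 0.12 and dystrophin Dmd at -0.90 ± 0.16 (1 of its 2 retained probes passed). Of 16 glycolysis and glycogen genes 2 were lower (adjusted p = 0.267), the phosphorylase kinase subunit Phkg1 at -0.88 ± 0.12 and the muscle phosphorylase Pygm at -0.74 ± 0.14. Oxidative phosphorylation had 1 of 33 genes lower (adjusted p = 0.753), Uqcrfs1, which lost its call under 2 of 12 alternatives, and fatty acid oxidation had 2 of 18 lower (adjusted p = 0.215), Cpt1b and Acadvl, which lost theirs under 6 and 4 of 16. With median scaling these 3 metabolic lists passed downward (camera adjusted p = 0.0117, 0.0489 and 0.0489), and with fry the glycolysis list did (adjusted p = 0.0377). Of 25 extracellular matrix genes 2 were higher and 2 lower (adjusted p = 0.869), with Ccn2 at 0.84 ± 0.23 and Col1a1 at -0.62 ± 0.18, calls lost under 6 and 8 of 16 alternatives. Adjusted over the list alone, these 6 lists had 2, 4, 0, 0, 0 and 2 genes higher and 3, 3, 4, 1, 2 and 2 lower, in the order given.

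Among cell type lists, 1 of 12 fibroblast markers was higher (camera adjusted p = 0.793; Mfap5, lost under 4 of 16 alternatives) and 1 of 10 adipocyte markers was higher (adjusted p = 0.403), the latter being Cidea, a lipid droplet protein, at 1.11 ± 0.14. Of 5 neutrophil, 5 erythroid and 7 Schwann cell markers 0 passed (adjusted p = 0.215, 0.753 and 0.321), and the erythroid list passed downward without transgenic Sample871 (camera adjusted p = 0.0195). S100a8, a neutrophil protein, had a log2 fold change of 2.25 ± 0.91 with an adjusted p of 0.135. Its log2 value was 10.21 in transgenic Sample871 and 6.01 and 5.92 in the other transgenic samples, and without Sample871 the log2 fold change was 0.83 and passed (limma adjusted p = 0.0103). The neutrophil list median fell from 0.61 to 0.03 without Sample871, and the list passed without Sample873, without Sample874 and with no detection filter (camera adjusted p = 0.0313, 0.0395 and 0.0438). Only 3 lymphocyte markers were measured, too few for the list test, and 2 of them were higher, of which Cd79b lost its call under 7 of 15 alternatives. Adjusted over the list alone, the fibroblast list had 1 gene higher and 1 lower, the adipocyte list 1 higher, the lymphocyte list 2 higher, and the neutrophil, erythroid and Schwann cell lists 0.

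Among the stress, handling and RNA lists, 3 of 17 cell cycle genes were higher and 1 lower (camera adjusted p = 0.166, but 0.0417 with no detection filter and 0.0212 with fry), including the replication helicase subunits Mcm5 (0.91 ± 0.13) and Mcm6 (0.98 ± 0.17). The lower gene, Aurka, lost its call under 11 of 15 alternatives, and Top2a, above background on none of the wild type arrays and at least 1.03-fold higher, under 4 of 12. Of 20 integrated stress and unfolded protein response genes 2 were higher and 3 lower (adjusted p = 0.988), with Psat1 at 1.14 ± 0.14 and Shmt2 at -0.94 ± 0.14 (-0.57 with its probes averaged), both enzymes of serine metabolism. Of 12 circadian genes 1 was higher, Arntl at 0.75 ± 0.13, and 2 were lower (adjusted p = 0.753). The lower genes were Bhlhe40 (-0.61 ± 0.12) and Nr1d1 (-0.53 ± 0.15, 3 of 3 retained probes past the threshold). Arntl and Bhlhe40 kept their calls under all 16 alternatives, and Nr1d1 lost its call under 6 of 16. Muscle splicing regulators had 1 of 12 higher and 1 lower (adjusted p = 0.873), Celf1 at 0.94 ± 0.13 and Celf2 at -0.45 ± 0.12. For Celf1 2 of 4 retained probes passed, and with its probes averaged its log2 fold change was 0.43 (limma adjusted p = 0.0222). The Celf2 call was lost under 7 of 16 alternatives, 1 of its 3 retained probes passed, and with its probes averaged its log2 fold change was -0.06 (limma adjusted p = 0.768). Core spliceosome genes had 3 of 33 higher (adjusted p = 0.262; Snrpd1, Sf3a3 and Prpf3 lost their calls under 5, 3 and 2 of 16 alternatives), nucleolus and ribosome biogenesis genes 0 of 20 (adjusted p = 0.777), and mouse counterparts of genes near human FRG1 had 1 of 7 lower (adjusted p = 0.928), the nucleotide carrier Slc25a4 at -0.48 ± 0.14 (limma adjusted p = 0.0498, a call lost under 8 of 16 alternatives). Adjusted over the list alone, these 7 lists had 5, 3, 1, 2, 3, 0 and 0 genes higher and 2, 3, 2, 2, 0, 0 and 1 lower, in the order given.

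A last list holds genes that the study's group has reported for muscle of FRG1 mice, and it is not independent evidence of direction. Of its 7 measured genes 4 were higher and 1 lower (4 and 2 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.215), though it did with fry (adjusted p = 0.0233). Eid3 was above background on none of the wild type arrays and was at least 1.37-fold higher in transgenic muscle (limma adjusted p = 0.00153). Kmt5b, a histone H4 methyltransferase, had a log2 fold change of 0.46 ± 0.13 (adjusted p = 0.0479), and its call was lost under 8 of 16 alternatives, with adjusted p-values from 0.0299 to 0.191. Rbfox1, a splicing regulator of muscle, had -0.49 ± 0.16 and did not pass (adjusted p = 0.0655), and it passed under 7 of 16 alternatives, with adjusted p-values from 0.00898 to 0.184.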

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

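All alternatives here were planned before the data were examined. The direction of the 11 shifted lists was kept under each of the 16 alternatives. Of the 24 genes with the largest changes, 15 had a value under all 16 alternatives and 9 under fewer, at least 12, and all 24 kept direction and call wherever they had a value. Of the 97 named genes past the threshold, 50 kept their call under all 16 alternatives, 14 kept it under the fewer alternatives that retained them, and 33 lost it under at least 1. Of the 45 not past it, 18 passed under at least 1, and 6 that passed under none changed sign (Camp, Ddx21, Slc4a1, Thrsp, Tnnt3 and Xist). No named gene past the threshold changed sign, but 28 had a log2 fold change over 1.5 times smaller under at least 1, 19 of them with an offset of 50 and 10 with probes averaged (Abcc9, Celf1, Celf2, Kmt5b, Mdm2, Ncam1, Prpf3, Sf3a3, Shmt2 and Zfp365). With median scaling, which leaves the shape of each array's distribution as measured, the probes lower in transgenic muscle numbered 507 and the genes lower in transgenic muscle 280, against 1313 and 744, and the cause was not tested. Averaging the probes of a gene gave 1699 genes, to be set against 1519 genes and not against the 2702 probes, since it tests 10287 genes and leaves out probes without a symbol, 620 of the changed ones among them. Lists called by camera with an estimated correlation numbered 0. Leaving out each sample in turn, the probes changed ranged from 1161 to 2660, the probes higher from 621 to 1442 and the probes lower from 534 to 1218. In the same fits the genes changed ranged from 651 to 1448, the genes higher in transgenic muscle from 353 to 819 and the genes lower in transgenic muscle from 298 to 629, and the shifted lists from 9 to 12. The lowest counts came without transgenic Sample873 or transgenic Sample871, where 639 and 657 of the 1519 genes remained called, in fits with fewer samples. The medians of 5 of the 11 shifted lists moved by over 1.5 times: with no detection filter to 0.15 for p53 targets, 0.12 for heat shock genes and 0.20 for immediate early genes, without transgenic Sample871 to 0.48 for the regeneration list, and for the interferon list to between 0.01 (without wild type Sample906) and 0.25 (median scaling). List calls were lost for slow fibre genes under 5 alternatives, for heat shock genes with median scaling and for the interferon list under 2. List calls also appeared: with median scaling the fast fibre, glycolysis, oxidative phosphorylation and fatty acid oxidation lists passed downward, with no detection filter the neutrophil and cell cycle lists passed upward, without transgenic Sample873 or transgenic Sample874 the neutrophil list did, and without transgenic Sample871 the erythroid list passed downward. With fry the slow fibre list was lost, and the fast fibre and glycolysis lists (downward) and the cell cycle list and the list of genes reported by the study's group (upward) passed. The slide block was not run because the tables name no slides. Signal over background limits what can be seen: probes under the detection threshold, that of Frg1 among them, gave no fold.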

Other observations

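The genes in this and the next paragraph were chosen after their values were seen. Several single genes of acetylcholine receptors or of the neuromuscular junction differed, in both directions, and they were not tested as a group. Chrna9, an acetylcholine receptor subunit, was 5.16-fold higher in transgenic muscle (above background on 2 of 3 wild type arrays; limma adjusted p = 3.50e-05). Chrne, the adult receptor subunit that takes the place of Chrng after birth, had a log2 fold change of -0.96 ± 0.13 (SE), and Prima1, which anchors acetylcholinesterase, had -1.22 ± 0.13 (above background on 2 of 3 transgenic arrays). Chrnd (0.41 ± 0.15) and Chrnb1 (-0.19 ± 0.12) did not pass. Ryr1, the calcium release channel, had -1.05 ± 0.12, with 2 of its 4 retained probes past the threshold, and the calcium-dependent kinase gene Camk2d had 2.07 ± 0.11, with 4 of 7.

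Some single genes of glutathione use, metal binding and redox repair were higher, among them Gsta2 (2.92-fold, 2 of 2 probes, above background on 1 of 3 wild type arrays, so that its size is uncertain), Mt3 (3.76-fold) and Srxn1 (1.82-fold, 3 of 3 probes), with no test of a group. Gstp3 and Gsta1 were above background on none of the wild type arrays and were at least 2.56-fold and at least 1.93-fold higher. Gstm2 went the other way (-0.70 ± 0.12, 3 of 3 probes). The overlapping imprinted transcripts Snrpn and Snurf had log2 fold changes of -1.16 ± 0.12 and -1.13 ± 0.23, and probes for the one can bind the other. Sox11 (5.59-fold, 3 of 3 probes, above background on 2 of 3 wild type arrays), Mybph (5.55-fold), Fhl2 (4.90-fold) and Trp63, a p53 relative (3.24-fold), were also higher. Each of these genes called here kept its direction and its call under the 6 background corrections and scalings compared.

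Of the tests that follow, those on macrophage and class II genes, on dividing cells and on histone families were chosen only after the result was seen. Wild type Sample923 stood apart from the other wild type samples: 370 probes lay over 1 log2 unit from the mean of the other samples of its group, against 18 to 49 for each other sample, and Pdk4 (3.63-fold) and Xist (3.28-fold) were among its lower genes. The tables argue against a mislabelled sample, since 15.1% of the 1448 genes called without it lay nearer the transgenic mean in it. On cooling the values are divided, and the question stays open. Cirbp lay 0.0639 log2 units from the other wild type samples and within the range of the 5 other samples, the outcome set beforehand as against cooling. The 2 Rbm3 probes disagreed. The dimmer of them was above background on only 3 of the 6 arrays, with log2 values of 7.79 in wild type Sample923 and 8.07 in transgenic Sample871. It was below background in wild type Sample906 and wild type Sample872, so no size is given. The other was detected on all 6 arrays and lay at -0.20 from the other wild type samples, with its lowest value, 8.76, in Sample923. For a loss of transcripts of long genes, the deviation of Sample923 from the 5 other samples was correlated with gene span across genes. The Spearman rho was -0.0382, above the bound of -0.1, the outcome set beforehand as against such a loss. It missed the bound by less than the spread between the other samples (SD 0.0644). Against its own group alone, a version computed first that was not the planned one, rho was -0.101, the lowest of the 6 samples. The question is left open, a choice made after both values had been seen. Genes are not independent replicates, and gene span is a weak stand-in for transcript length.

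Of 14 macrophage markers 12 were higher past the threshold, as were 3 class II genes and Cd74, while 3 of 15 endothelial, 4 of 12 smooth muscle and 6 of 9 tendon markers were lower past it and none higher, and with an estimated correlation none of these lists, nor the interferon list that holds the class II genes, passed (camera adjusted p = 0.25 for each). On its own, a smaller share of fibre RNA would raise all of these, and the mean score of the 3 latter lists was instead -0.43 ± 0.03 log2 units (SE). These 3 lists were taken because they were lower, so the score only describes them. It cannot tell whether the fibre share changed together with other shifts. The fibroblast, extracellular matrix and adipocyte lists, left out of the score, had medians of 0.07, -0.05 and 0.08. A chromosome segment carried with the transgene that changed only its own genes cannot be the whole cause of the rise in these 4 genes. Cd74, on another chromosome than the 3 class II genes, rose by 1.54. An effect of such a segment on genes elsewhere was not tested and stays open. The median of the class II genes and Cd74 exceeded the macrophage median by 0.88, against an SD of 0.55 among macrophage markers. Most macrophage markers thus rose less, but Lgals3 rose by 2.59, more than any of the 4, and the next highest, Lyz2, by 1.06. With markers so unequal, the gap cannot decide whether a rise in macrophage number was the whole cause of the class II rise. A change in the kind or state of antigen-presenting cells, or class II expression by another cell type, may contribute and was not tested, and the genotype remains among the open explanations.

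Among replication-dependent histone genes, which were no planned list and were not tested for enrichment, the calls lay mainly in the H2A family. Of 37 measured genes 15 passed upward and 0 downward (7.53% of all genes passed upward), with 10 of the 11 H2A genes and 5 of the 26 others among them, and 16 of 37 passed upward under each of the 5 other scalings. The low values of wild type Sample923 are not the source of the histone median, which without it was 1.65 times its value with it. Without it 15 of the 37 genes still passed upward. That median covers many genes that did not pass, so it does not show how far single H2A changes depend on Sample923. In the H2A genes with the largest changes, the log2 value of Sample923 was the lowest of the wild type samples. These were H2ac12 (5.31 against 6.59 and 6.69), H2ac15 (5.96 against 6.72 and 6.57), H2ac13, H2ac6 and H2ac23, and its low values add to their fold changes. Among the other called H2A genes it was the highest in H2ac10 (11.40 against 11.16 and 11.21) and in between in H2ac18, H2ac19, H2ac20 and H2ac22. Probes shared within a single family cannot account for the whole pattern, since 4 families held a gene past the threshold, but how many separate H2A transcripts lie behind the 10 was not tested. More dividing cells may contribute and stay open: the median of all 37 histone genes exceeded the cell cycle median by 0.0758, or by 0.123 with genes below background in 1 group at their bounds, but families differed, with medians of 0.69 for H2A, 0.46 for H3, and 0.07 for both H2B and H4, and the H2A median exceeded the cell cycle median by 0.61 (SD of single cell cycle genes 0.41), while Mcm5 and Mcm6 rose and the cell cycle list passed only with no detection filter or with fry. No explanation from the genotype was tested.

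The 6 samples make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 2702 probes and 1519 genes and was in both cases the 1 of the 10 splits with so many, and the highest of the others gave 0 of each in limma (879 probes and 415 genes at an unadjusted p under 0.05, against 5579 and 3136). Each of the others mixed the genotypes, so a real difference would widen the spread within their groups and lower their counts. They do not show the counts without a group difference. For gene lists, 2 of the 10 splits gave as many as the real one, which gave 11, and the highest other gave 12. That split set wild type Sample906, wild type Sample923 and transgenic Sample873 against the rest. The remaining splits gave from 2 lists upward. By size of median shift, 10 of the 11 shifted lists were largest in the real split, and the exception was the interferon list. These lists were chosen by their calls in that split, so the ranking is no separate support. Of the 9 other splits, 7 also called the macrophage list, 6 the denervation list, and 5 each the regeneration and endothelial lists. The slow fibre and immediate early lists were called in 3 each. The tendon, p53, heat shock and interferon lists were called in 1 each, and the smooth muscle list in 0.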
